A study of Danio rerio with 4 samples.

How the data were processed

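RNA was measured in 4 libraries of pooled zebrafish (Danio rerio) hearts, dissected by hand at 48 hours post fertilisation (hpf) from fish carrying a kdrl:eGFP transgene, which marks endothelial cells. Of these, 2 came from tie1 mutants and 2 from sibling controls. The sample labels call the controls wild type, while the series' design text speaks of both wild-type and heterozygous siblings, so the controls are called siblings here. Per the labels' protocols, total RNA was treated with DNase and 2 ng went into a stranded total RNA kit for very small inputs (SMARTer Stranded Total RNA-Seq Pico). Such a kit primes from total RNA, so ribosomal RNA transcripts can take a large part of the reads. The number of hearts in a pool is not given in the sources used here, and beyond the labels nothing says that the replicates came from separate clutches. The p-values measure the spread between these pools, which can be technical.

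The submitters' processing notes name FastQC, STAR 2.4.0a, featureCounts 1.4.5-p1 and Subread, and the genome build GRCz11 (danRer11), without giving each tool's role. The strand setting of the counting, the normalization method and the filter on genes are not given in the sources used here. The authors deposited one table of the whole series, called a normalised count matrix, with 16662 genes, of which 16169 are protein coding. Its lowest row total is 4. The deposited values are whole numbers, but they were treated as a score without a fixed unit and not as raw reads. The spacing of the low values differs between libraries, as it would if reads per gene were divided by a factor for each library and then rounded. That spacing was fitted first to values up to 400 and then refined on a wider range of values. The fit gave factors of 0.904 and 0.75 for the mutant libraries and 1.341 and 1.146 for the sibling libraries. Where the factor is above 1, rounding merges neighbouring read numbers, so reads could not be recovered and no test for read counts was used. The design fixed beforehand foresaw this unit and the test used for it.

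The normalised totals were 2648465 and 2365615 in the mutant libraries and 2413086 and 2154702 in the sibling libraries. Multiplied by the fitted factors, they correspond to an estimated 2390000, 1770000, 3240000 and 2470000 assigned reads in mutant 1, mutant 2, sibling 1 and sibling 2. At this depth the median gene of the table had a value of 24 or 25, so a large part of the genes rests on few reads. The files give no molecular identifiers, and the values cover neither duplicate reads nor loss of RNA before sequencing.

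Values were analysed as log2(value + 1), and a fold change is on that scale, which understates changes of low genes. Genes with a mean of at least 10 over the 4 libraries were kept, which left 12118. Mutant and sibling libraries were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Every adjusted p of a gene comes from this test unless another is named, errors of log2 fold changes are standard errors (SE), and SD is the standard deviation over the 2 libraries of a group. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so none is used for single genes. The fit was tested on simulated values for the same 12118 genes, with 200 changed genes in each of 5 draws. It called 1.6% of the genes changed 2-fold, 58.5% of those changed 4-fold, 81.2% at 8-fold and 94.4% at 16-fold, and 21 of 57900 unchanged genes. The changed genes were split equally over these 4 sizes, and strongly changed genes ease the adjusted threshold for the rest. Simulated genes also varied independently of each other, so these shares may be too high for the pools compared here.

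Gene lists were fixed before the data were examined, 34 in all, 22 for pathways and processes and 12 for cell types and tissues other than heart muscle and endothelium. Each list with at least 5 tested genes was compared with the other genes by limma's camera, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 32 lists tested. Camera with an estimated correlation and fry stand beside it. With 2 libraries in each group, camera with an estimated correlation has few degrees of freedom and could hardly call any list or term. Where a list is said to fall, rise or be called, this refers to camera with the preset correlation unless another test is named. Fry tests whether the genes of a list move, on balance, 1 way. For each list the number of members past the threshold adjusted over the list alone is given too. The preset correlation takes the genes of a list as nearly independent, and genes that vary together because the pools differ in tissue content break that assumption. The annotation columns of the table gave Gene Ontology terms for 7021 genes and KEGG pathways for 4162, and the 2278 terms with 10 to 300 tested genes were tested in the same way.

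The genes named follow a rule fixed before the data were examined. It takes tie1, then 22 fixed genes of endothelium, cardiac jelly and heart muscle where tested, and then up to 12 genes in each direction with the largest change past the threshold and a mean of at least 50, a symbol that is not a clone name and groups that do not overlap. If fewer pass, the rule takes the smallest p-values, which was the case for all 24. Last come up to 4 members of each list past the threshold, or its 2 most abundant ones where none passes. Of the fixed genes, angpt2a was not tested, and the ventricular myosin gene often called vmhc is listed in the table as myh7. Genes outside the rule are named as chosen after their values were seen.

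Gene names were those of the table, and 382 rows share a symbol with another row, such as the 2 rows of actc1a. Counting can split reads between near-identical copies, such as myh7 and its neighbour myh7l, the globin genes and the myhz1 genes, whose single values are therefore uncertain. Since the strand setting is not known here, reads of overlapping or antisense genes may also be mixed. No column of other samples was present (0). Alternatives were another pseudocount (0.5 and 10), no filter or a mean of at least 50, rescaling by trimmed mean of M values (TMM), quantile normalization, other variance models, a fold change of at least 2, the replicate number as a block, other set tests and each library left out. Plots were drawn with matplotlib 3.10.9, and other tests used scipy 1.17.1.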

Results

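The data were normalised gene values from 4 libraries of pooled zebrafish hearts taken at 48 hpf, 2 from tie1 mutants and 2 from sibling controls. The gene tie1 encodes an orphan receptor tyrosine kinase of endothelial cells and of endocardium, the endothelium that lines the heart, and the comparison asks which genes of the heart differ when it is mutated. The libraries held an estimated 1770000 to 3240000 assigned reads and between 16276 and 16482 detected genes. Mitochondrial ribosomal RNA took 43.4% and 37.6% of the normalised total in the mutant libraries, against 32.9% and 30.4% in the sibling libraries. The 10 highest genes took 49.8% and 45.3%, against 42.3% and 38.1%. Across genes, the log2 values of the 2 mutant libraries correlated at 0.922 and those of the 2 sibling libraries at 0.941, while pairs from different groups lay between 0.909 and 0.932, and genes are not independent replicates.

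In the mutant hearts, tie1 itself was lower in both libraries, with normalised values of 123 and 88 against 558 and 300 in the siblings. That is a mean of 105.5 ± 24.7 against 429 ± 182 (SD, n = 2 each), a log2 fold change of −1.97 ± 0.31 (SE), or a fold of 0.256, with an adjusted p of 0.148 in limma. The gene (ENSDARG00000004105) lies on the minus strand of chromosome 6, positions 33979523 to 34008901 of GRCz11. The libraries labelled as mutant therefore had the lower tie1 values, though the difference did not pass the threshold over all genes. It passed with genes of a mean of at least 50 (adjusted p = 0.0431) and with limma's robust setting (adjusted p = 0.0413), and without 1 library it ranged from 0.659 to 0.902. Relative to cdh5, the gene of VE-cadherin, an adhesion molecule of all endothelium, the tie1 value was 0.0937 and 0.111 in the mutants and 0.296 and 0.269 in the siblings. This ratio was chosen after the values were seen.

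No gene passed the threshold between mutants and siblings. The smallest p-values belonged to erythrocyte genes with lower values in the mutants, led by slc4a1a, the anion exchanger of the red cell membrane, at a log2 fold change of −1.85 ± 0.21. The smallest p in the other direction belonged to tg, the gene of thyroglobulin, the precursor protein of thyroid hormone, at 2.83 ± 0.39. With limma, 0 of 12118 genes were past the threshold and the smallest adjusted p was 0.074. At an unadjusted p under 0.05, 316 genes were higher and 526 lower, 842 together, where chance alone gives about 606. Groups did not overlap for 15.7% of genes with higher and 18.3% with lower mutant values, against 16.7% by chance in each direction. Without mutant 2, 185 genes were higher at that unadjusted p, and without sibling 1, 154 were lower. Other settings called more, with 8 genes after TMM scaling, 13 among genes with a mean of at least 50 and 16 with the robust setting, and an adjusted p under 0.1 gave 7 genes, 1 higher and 6 lower.

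As none passed, the 12 genes named in each direction are those with the smallest p. Among the higher genes after tg, with 279 and 173 against 45 and 20 and an adjusted p of 0.0954, came igfbp1a, which encodes a secreted protein that binds insulin-like growth factors, with 94 and 64 against 22 and 24 and a log2 fold change of 1.71 ± 0.30. The endothelin genes edn1, at 1.05 ± 0.27, and edn2, at 1.23 ± 0.33, encode vasoactive peptides. The apolipoprotein gene apoeb stood at 0.81 ± 0.21 and the complement gene c9 at 1.59 ± 0.42. The remaining log2 fold changes were 1.28 for pkig, 1.44 for pclob, 1.04 for il16, 0.99 for swap70b, 0.94 for dhx36 and 1.0 for the protocadherin gene pcdh19, with adjusted p from 0.21 to 0.445. Of the 12 with lower values, 7 belonged to the fixed list of erythrocyte genes and 2 to that of skeletal muscle: ckmb, a muscle creatine kinase, with 29 and 29 against 110 and 114 and −1.91 ± 0.25, and the fast myosin gene myhz1.1, with −1.94 ± 0.31. The others were tie1, tubb1, a beta-tubulin gene, with −1.78 ± 0.25, and and2, an actinodin gene of the fin fold, with −2.03 ± 0.32.

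**Figure D1:**
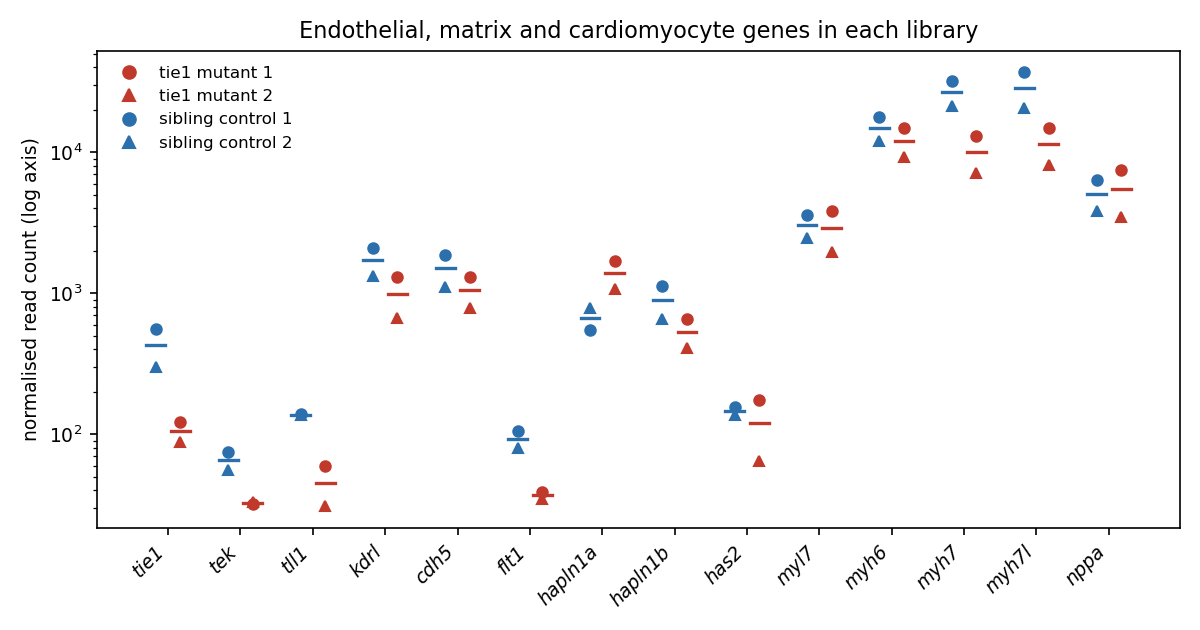
Normalised read count per library (log axis) for 14 endothelial, matrix and cardiomyocyte genes; circles are replicate 1, triangles replicate 2, blue the sibling controls, red the tie1 mutants, and bars the means of 2 libraries. Both mutant values of tie1 (123 and 88) lie below both sibling values (558 and 300), as do those of myh7 and myh7l, while myl7 and nppa overlap between the groups.

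Erythrocyte genes fell as a list in the mutant hearts. Of 22 tested members, 21 were lower, with a median log2 fold change of −1.26, a fold of 0.419, and 21 had both mutant values below both sibling values. Camera gave an adjusted p of 1.71e-32, and the adjusted p = 0.512 with an estimated correlation. Adjusted over the list alone, 20 fell, 0 rose and 2 did not pass, while over all genes 0 passed. The heme synthesis gene alas2 had values of 206 and 189 against 850 and 649, the transferrin receptor gene tfr1a 87 and 72 against 320 and 270, and slc4a1a 300 and 363 against 1253 and 1129. The membrane skeleton gene epb41b changed by −1.48 ± 0.21, nt5c2l1 by −1.85 ± 0.30 and the globin genes hbbe1.2 by −1.40 ± 0.21 and hbae1 by −1.50 ± 0.24, all past the threshold adjusted over the list alone. The most abundant members, sptb, the gene of a spectrin, and hbae3, a globin gene, stood at −1.15 ± 0.27 and −1.14 ± 0.22. The 2 that did not pass, named after their values were seen, were the erythroid transcription factor genes gata1a, at −0.45 ± 0.35, and klf17, at 0.34 ± 0.30. The median of the list was −1.28 in mutant 1 and −1.27 in mutant 2 relative to the sibling mean, and the call held without each library in turn (adjusted p from 2.7e-17 to 6.8e-13). Reads may be split between globin copies, so their single values are uncertain.

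**Figure D2:**
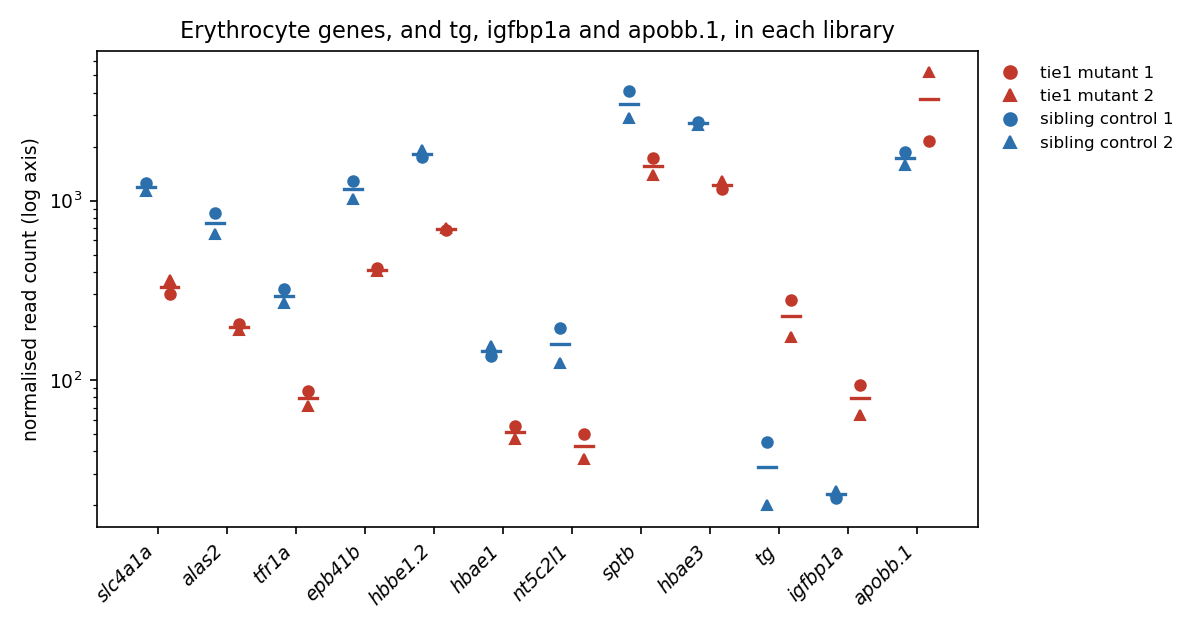
Normalised read count per library (log axis) for 9 erythrocyte genes and for tg, igfbp1a and apobb.1, with symbols, colours and mean bars as in the plot of endothelial and muscle genes. For each erythrocyte gene both mutant libraries lie below both sibling libraries, for example alas2 at 206 and 189 against 850 and 649, while apobb.1 is highest in mutant 2, at 5197.

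Genes of the angiopoietin and Tie receptor system and of endothelium fell as lists in camera with the preset correlation, but not with an estimated one or in fry. In the Angiopoietin-Tie list, which does not count tie1 itself, 10 of 11 tested genes were lower, with a median of −0.44. Its camera adjusted p was 0.00119, and the adjusted p = 0.607 with an estimated correlation. None of the 11 passed adjusted over the list alone or over all genes. The receptor gene tek, also known as tie2, had values of 32 and 33 against 75 and 56 and a log2 fold change of −0.97 ± 0.28. The ligand genes angpt1 and angpt2b stood at −0.29 ± 0.20 and −0.44 ± 0.52, and the transcription factor gene foxo3b at −0.64 ± 0.21. Of the 31 pan-endothelial genes, 28 were lower, with a median of −0.47, an adjusted p of 1.44e-06 and an adjusted p = 0.607 with an estimated correlation. The VEGF receptor gene kdrl, which drives the transgene of these fish, had −0.84 ± 0.35 and cdh5 had −0.51 ± 0.32. The gene that fell adjusted over the list alone was flt1, a VEGF receptor gene chosen after its values were seen, with 39 and 35 against 106 and 80 and −1.29 ± 0.27. The VEGF pathway list, which shares kdr, kdrl and flt1 with it, had 9 of 11 genes lower, a median of −0.27, an adjusted p of 0.0216 and an adjusted p = 0.607 with an estimated correlation. There, 1 gene fell adjusted over the list alone (flt1), and the abundant co-receptor gene nrp1a stood at −0.13 ± 0.21.

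These vascular calls were lost without some of the libraries, while the direction stayed lower in each such fit. The Angiopoietin-Tie list was at an adjusted p of 0.11 without mutant 1 and 0.12 without sibling 1, and the pan-endothelial list at 0.40 without mutant 2 and 0.097 without sibling 1. The VEGF list was at 0.11 without mutant 1, 0.21 without mutant 2 and 0.12 without sibling 1. The medians relative to the sibling mean were −0.61 in mutant 1 and −0.31 in mutant 2 for the Angiopoietin-Tie list, with the siblings at 0.21 and −0.21, and −0.34 and −0.22 for the VEGF list, with the siblings at 0.14 and −0.14. The pan-endothelial median was −0.14 in mutant 1 and −0.79 in mutant 2, relative to the sibling mean. The 2 sibling libraries themselves lay at 0.26 and −0.26, so mutant 1 lay above sibling 2. In 12 of the 31 pan-endothelial genes both mutant values lay below both sibling values, and in 0 above. The ratio of cdh5 to the pan-cardiac myosin light chain gene myl7, chosen after its values were seen, was 0.342 and 0.402 in the mutants and 0.524 and 0.452 in the siblings.

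Genes of the endocardium and valves passed no test as a list. In the list of 30, 21 were lower, the median was −0.16 and the camera adjusted p was 0.166. The list leaned lower without mutant 1 and without sibling 2, but higher without mutant 2 and without sibling 1. Its library medians were 0.02 in mutant 1 and −0.26 in mutant 2, with the siblings at 0.16 and −0.16. The transcription factor gene nfatc1, a marker of endocardium, had 165 and 147 against 195 and 135, a log2 fold change of −0.06 ± 0.25. The receptor gene notch1b stood at −0.62 ± 0.28 and the matrix gene postnb at 0.24 ± 0.27. Flow-responsive genes had a median of −0.22 over 20 members and an adjusted p of 0.0522, with 0.0036 without mutant 1, 0.029 without sibling 2 and 0.048 with a pseudocount of 10. Of these, klf2a stood at −0.56 ± 0.29, klf2b at −0.27 ± 0.25 and the kinase gene prkd2 at −0.42 ± 0.27. Here edn1 rose adjusted over the list alone and cyp1b1, a cytochrome P450 gene chosen after its values were seen, fell, with 38 and 32 against 118 and 95. The Notch pathway list had an adjusted p of 0.907 over 22 genes, with a median of −0.10 and a mean of 0.03, and notch3 stood at −0.34 ± 0.20. The BMP and TGF-beta list had an adjusted p of 0.975 over 34 genes, with a median of 0.03 and a mean of −0.03, where bmp4 stood at −0.28 ± 0.29 and fstl1b at −0.42 ± 0.30. In that list 1 gene fell adjusted over the list alone, tll1.

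Genes of the extracellular matrix fell as 2 lists. Of 38 genes of basement membrane and fibrillar matrix, 30 were lower and 23 had both mutant values below both sibling values, with a median of −0.36. The adjusted p was 1.47e-08, and the adjusted p = 0.512 with an estimated correlation. None passed adjusted over the list alone. The median was −0.42 in mutant 1 and −0.35 in mutant 2 relative to the sibling mean, and the call held without each library (adjusted p from 1.5e-07 to 0.00024). The most abundant members were the fibrillin gene fbn2b, with 1441 and 1562 against 2638 and 2257 and −0.70 ± 0.23, and the collagen gene col1a1b, with −0.28 ± 0.22. The basement membrane collagen genes col4a1 and col4a2 and the fibronectin gene fn1a, chosen after their values were seen, stood at −0.90 ± 0.25, −0.86 ± 0.21 and −0.75 ± 0.21.

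Among 25 matrix proteases and inhibitors, 17 were lower, with a median of −0.18, an adjusted p of 0.0335 and an adjusted p = 0.607 with an estimated correlation. In this list 4 genes fell adjusted over the list alone, and the last 3 of them were chosen after their values were seen. They were tll1, the gene of a tolloid-like metalloprotease, with 60 and 31 against 140 and 136 and −1.65 ± 0.32, mmp11a with −1.45 ± 0.32, mmp14b with −0.77 ± 0.22 and adamts9 with −1.0 ± 0.29. Of these, mmp14b and adamts9 passed only barely, with a limma p adjusted over the list that rounds to 0.05. For tll1 it was 0.0162 and for mmp11a 0.0207. The most abundant members, adam10a and adamts15a, stood at 0.02 ± 0.22 and −0.49 ± 0.20. This list was at an adjusted p of 0.46 without mutant 1, 0.12 without sibling 1, 0.21 without sibling 2 and 0.11 with no filter on low values. Its median was −0.42 in mutant 1 and −0.04 in mutant 2, with the siblings at −0.02 and 0.02, so without mutant 1 it came to −0.04. Genes of hyaluronan and proteoglycans, the main components of cardiac jelly, went both ways, with a median of −0.09 over 17 genes and an adjusted p of 0.45. The link protein gene hapln1a had 1696 and 1068 against 553 and 789, a log2 fold change of 1.03 ± 0.28, while its paralog hapln1b had −0.73 ± 0.31. The genes that passed adjusted over the list alone were 2 that rose, hapln1a and the hyaluronan receptor gene lyve1a at 1.13 ± 0.31, and 2 that fell, the hyaluronidase gene cemip at −1.22 ± 0.26 and the versican gene vcanb at −0.76 ± 0.22, of which only hapln1a was named by the rule. The hyaluronan synthase gene has2 stood at −0.45 ± 0.40 and the other versican gene, vcana, at 0.46 ± 0.28.

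Sarcomere genes fell as a list, with low values of the ventricular myosin heavy chain genes in both mutant libraries, while several abundant heart muscle genes overlapped between the groups. Of 30 tested genes 29 were lower, with a median of −0.56 and an adjusted p of 1.47e-08. The adjusted p = 0.607 with an estimated correlation, and without sibling 1 it was 0.079. The gene myh7, also known as vmhc, had 13077 and 7093 against 31906 and 21256, with −1.43 ± 0.43 and an adjusted p of 0.525, and its neighbour myh7l had 14781 and 8122 against 36842 and 20593, with −1.33 ± 0.46. They lie on the minus strand of chromosome 2, at 24252987 to 24270062 and 24274293 to 24289726, and reads could be split between them. The giant titin gene ttn.2 stood at −0.55 ± 0.46. By contrast, the atrial myosin gene myh6 had −0.32 ± 0.39, the pan-cardiac light chain gene myl7 −0.12 ± 0.35 and the natriuretic peptide gene nppa 0.05 ± 0.41, and under quantile normalization these 3 were 0.25, 0.01 and −0.11. Adjusted over the list alone 1 fell, the less abundant of the 2 rows called actc1a, chosen after its values were seen, with 2 and 8 against 54 and 44, and reads could be shared between these copies. The list's median was −0.25 in mutant 1 and −0.66 in mutant 2 relative to the sibling mean, with the siblings at 0.28 and −0.28, so mutant 1 lay above sibling 2. In 12 of the 30 genes both mutant values lay below both sibling values, and in 1 above. Within libraries, the ratio of myh7 to myl7, chosen after its values were seen, was 3.40 and 3.61 in the mutants and 8.88 and 8.61 in the siblings.

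Other heart genes were less uniform. Calcium handling and natriuretic peptide genes had a median of −0.28 over 15 genes and a camera adjusted p of 0.061, or 0.025 with no filter. The list stayed lower without mutant 1 and without sibling 2, but turned higher without mutant 2 and without sibling 1. The calcium release channel gene ryr2b stood at −0.52 ± 0.33. Cardiac transcription factor genes had a median of −0.14 over 26 genes and a camera adjusted p of 0.0878. Their list turned higher without sibling 1 and stayed lower without each of the other libraries. In it hand2 stood at −0.25 ± 0.21 and gata5 at −0.51 ± 0.24. The trabeculation and growth factor list fell, with 18 of 23 genes lower, a median of −0.12 and an adjusted p of 0.0117. The adjusted p = 0.607 with an estimated correlation, and it was 0.10 without mutant 1 and 0.12 without sibling 1, with library medians of −0.26 and −0.16 in the mutants and 0.09 and −0.09 in the siblings. Its fixed genes passed no test, where erbb2 stood at −0.15 ± 0.23, nrg2a at −0.01 ± 0.31 and bmp10 at 0.11 ± 0.38, and its most abundant ones, fgfr2 and apln, at −0.31 ± 0.21 and −0.56 ± 0.26. Adjusted over the list alone 1 fell, the guidance factor gene sema3e, chosen after its values were seen, with 13 and 13 against 39 and 46.

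Lists of metabolism and growth moved in both directions. Of 31 hypoxia and glycolysis genes 26 were lower, with a median of −0.28, an adjusted p of 0.000501 and an adjusted p = 0.607 with an estimated correlation, and it was 0.12 without sibling 1. The library medians were −0.34 and −0.37 in the mutants and 0.16 and −0.16 in the siblings. There aldoaa had −0.69 ± 0.25 and gapdh −0.06 ± 0.30 (0.14 under quantile normalization), and the gene that rose adjusted over the list alone was igfbp1a. The list of cytosolic ribosomal protein genes rose as a set, with positive log2 fold changes in 84 of 89 members, a median of 0.28, an adjusted p of 1.6e-09 and an adjusted p = 0.607 with an estimated correlation. Without sibling 1 it was 0.56, and none passed adjusted over the list alone. In 20 of the 89 both mutant values lay above both sibling values, and the medians relative to the sibling mean were 0.13 in mutant 1, 0.41 in mutant 2, −0.28 in sibling 1 and 0.28 in sibling 2, so sibling 2 lay above mutant 1. The abundant rpl3 and rpl4 stood at 0.32 ± 0.26 and 0.22 ± 0.25, and the list, drawn up by name, also took in rps6ka1, a kinase gene chosen after its values were seen, at 0.93 ± 0.43. All 13 protein genes of the mitochondrial genome were higher, with a median of 0.48, an adjusted p of 2.47e-06 and an adjusted p = 0.607 with an estimated correlation, and without mutant 1 it was 0.071. The median was 0.75 in mutant 1 and 0.24 in mutant 2, with the siblings at 0.14 and −0.14, beside the mitochondrial ribosomal RNA at 43.4% and 37.6% of the mutant totals against 32.9% and 30.4%. Here mt-co1 had 0.79 ± 0.32 and mt-nd5 0.35 ± 0.33. Nuclear genes of oxidative phosphorylation had a median of −0.06 over 85 genes and an adjusted p of 0.166, with 0.011 without mutant 1, and atp5fa1 and atp5f1b stood at −0.42 ± 0.21 and −0.60 ± 0.22.

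Cell cycle genes had a median of 0.12 over 36 genes and an adjusted p of 0.111, with 0.023 in the opposite direction without sibling 1, 5.3e-07 without sibling 2 and 0.046 under quantile normalization. The proliferation marker gene mki67 stood at 0.18 ± 0.27 and cenpf at −0.11 ± 0.28 (0.06 under quantile normalization). The p53 and apoptosis list had a median of −0.02 over 20 genes and an adjusted p of 0.657, and ccng1 stood at −0.15 ± 0.20. Immediate-early and heat shock genes had a median of 0.10 over 22 genes and an adjusted p of 0.166, with hsp90ab1 at 0.09 ± 0.29 (−0.02 under quantile normalization) and hspa5 at 0.32 ± 0.32. Interferon response genes had a median of 0.05 over 7 genes and an adjusted p of 0.276. There stat1a stood at 0.05 ± 0.27, and 2 rose adjusted over the list alone, socs3a with 91 and 48 against 26 and 14, and irf9, chosen after its values were seen, with 41 and 35 against 15 and 17.

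Markers of tissues other than heart differed between the pools, beside all the lists above. Skeletal muscle genes fell, with 26 of 28 lower, a median of −1.17, an adjusted p of 3.72e-16 and an adjusted p = 0.607 with an estimated correlation. Of the 28, 10 fell and 0 rose adjusted over the list alone, and the call held without each library (adjusted p from 1.5e-22 to 8.7e-05). The median was −2.02 in mutant 1 and −0.45 in mutant 2 relative to the sibling mean. The abundant acta1b and ckma stood at −0.66 ± 0.22 and −0.80 ± 0.22. The liver and yolk list rose as a set, with positive log2 fold changes in 24 of 24 members, a median of 1.0, an adjusted p of 1.01e-08 and an adjusted p = 0.607 with an estimated correlation. None of the 24 passed adjusted over the list alone, and 3 had both mutant values above both sibling values. Their median was −0.13 in mutant 1 and 2.17 in mutant 2, and without mutant 2 the list turned to the other direction with an adjusted p of 0.85. The apolipoprotein gene apobb.1 had 2160 and 5197 against 1865 and 1584, and apoa1b stood at 0.68 ± 0.40. The neural list rose as a set, with positive log2 fold changes in 15 of 16 members, a median of 0.81, an adjusted p of 3.45e-06 and an adjusted p = 0.607 with an estimated correlation. None of the 16 passed adjusted over the list alone, and 3 had both mutant values above both sibling values. The medians were 1.56 in mutant 1, 0.52 in mutant 2, 0.44 in sibling 1 and −0.44 in sibling 2. The adjusted p was 0.27 without mutant 1 and 0.11 without sibling 2, and nova2 and tubb5 stood at 0.33 ± 0.29 and 0.40 ± 0.26.

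The leukocyte list rose as a set, with positive log2 fold changes in 8 of 10 members, of which 4 had both mutant values above both sibling values, a median of 0.35, an adjusted p of 0.019 and an adjusted p = 0.607 with an estimated correlation, and it was 0.44 without mutant 2 and 0.096 without sibling 1. Its median was 0.23 in mutant 1 and 0.78 in mutant 2, with the siblings at −0.07 and 0.07. There srgn stood at 0.25 ± 0.32 and apoc1 at 0.59 ± 0.54, and none passed adjusted over the list alone. The pharyngeal arch and cartilage list rose as a set, with a median of 0.09 and a mean of 0.33. Log2 fold changes were positive in 15 of 24 members, and none passed adjusted over the list alone. Its adjusted p was 0.0216, and the adjusted p = 0.671 with an estimated correlation. Without mutant 2 it turned to the other direction at 0.53, and without sibling 1 it was 0.55, with medians of −0.12 in mutant 1 and 0.63 in mutant 2 and the siblings at −0.16 and 0.16. Here col11a1a stood at 0.09 ± 0.23 and col2a1b at −0.11 ± 0.25 (0.06 under quantile normalization). Not called were epicardium (median −0.24, adjusted p = 0.191, krt94 −0.28, sema3fb −0.20), smooth muscle and mural cells (−0.19, adjusted p = 0.302, myh11a −0.33), epidermis and epithelium (0.07, adjusted p = 0.534, krt4 −0.08, or 0.09 under quantile normalization, and krt8 −0.27) and pigment cells and neural crest (−0.53, adjusted p = 0.191, gmps −0.37, pmela −0.59). The epidermis gene and2 fell adjusted over the list alone. Without sibling 1 the epidermis list was at 0.023 in the opposite direction and without sibling 2 at 0.0029, and the pigment list was at 0.018 without mutant 2. Exocrine pancreas and gut had 4 tested genes, too few for the test, with fabp1b.1 at 0.42 and ela2l at −1.58, and of the lens list 0 genes were tested.

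**Figure D3:**
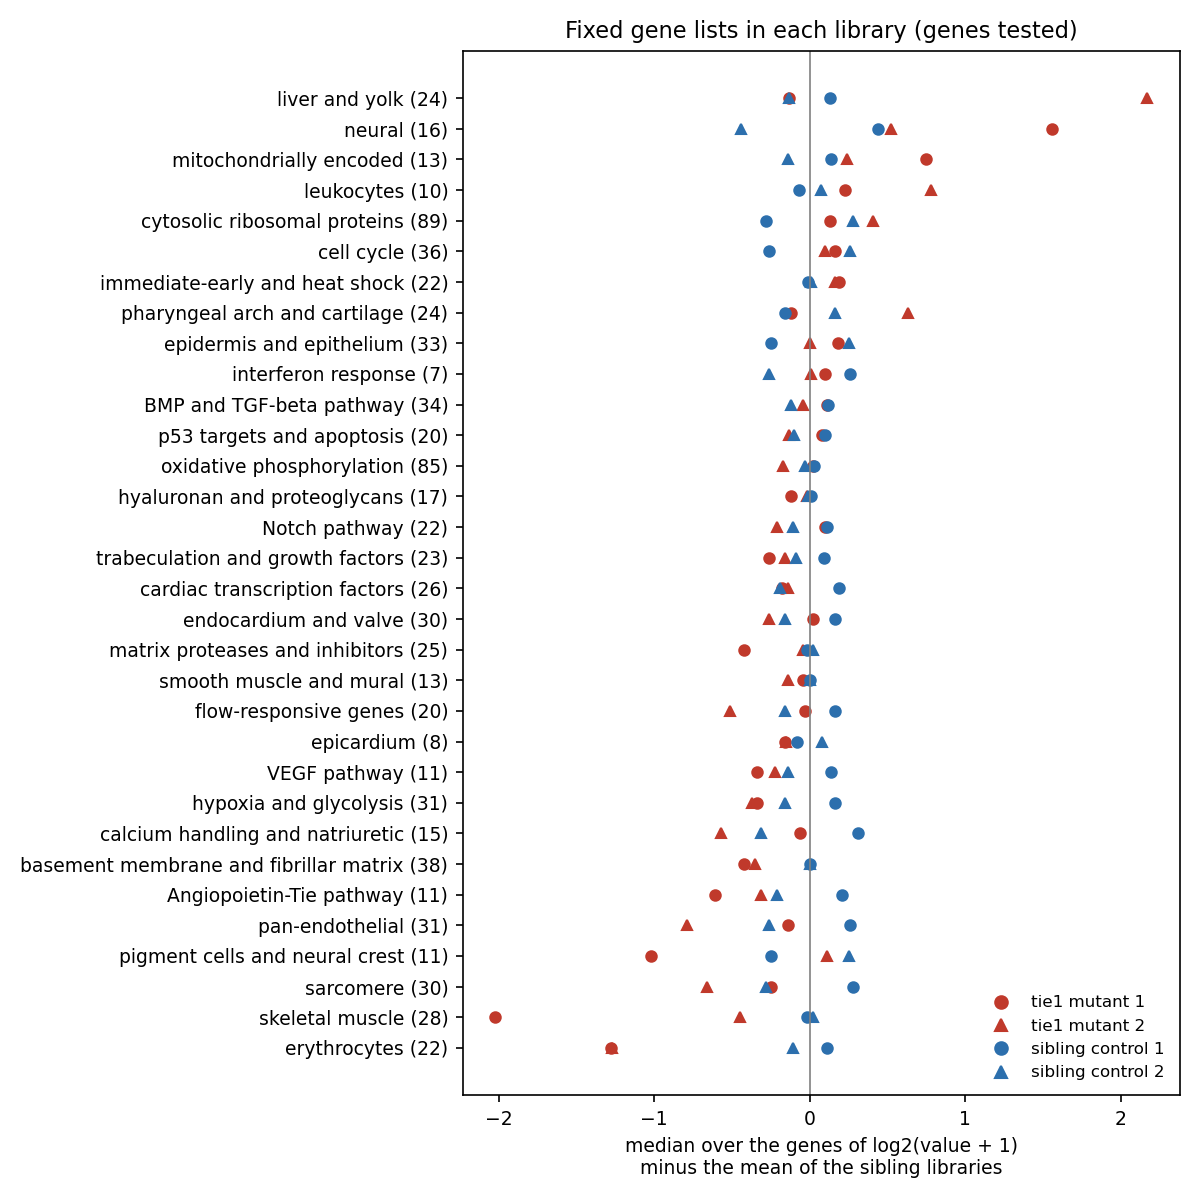
Median over each list's genes of log2(value + 1) minus the mean of the sibling libraries (horizontal axis, log2 units) for the 32 tested lists, with the number of genes tested in parentheses, circles for replicate 1, triangles for replicate 2, blue for siblings and red for mutants. Erythrocyte medians of the mutants coincide at −1.28 and −1.27, while liver and yolk lie at −0.13 and 2.17 and skeletal muscle at −2.02 and −0.45.

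In total, 16 of the 32 tested lists were called, 6 higher and 10 lower, with 0 called with an estimated correlation and 0 by fry. Among the called lists the estimated correlation ran from −0.03 for trabeculation to 0.85 for mitochondrially encoded genes, against the preset 0.01. It was 0.65 for pan-endothelial, 0.6 for sarcomere and 0.57 for Angiopoietin-Tie genes, but 0.14 for erythrocytes and 0.02 for basement membrane. Although the last was close to the preset value, the unadjusted camera p of basement membrane went from 2.76e-09 to 0.032. Camera with an estimated correlation draws its p from the few degrees of freedom that 4 libraries leave. It could therefore hardly call a list here whatever the correlation, and its lack of calls does not decide about any list. Leaving out 1 library gave between 8 and 20 called lists, and splitting the same 4 libraries by their number instead of by genotype gave 19. The annotation terms gave a like picture. Of 2278 terms, 39 rose and 66 fell, among them cytosolic ribosome (68 genes, median 0.28, adjusted p = 1.02e-05) and ribosome biogenesis (121 genes, 0.24, adjusted p = 0.000104) in the first group and embryonic hemopoiesis (38 genes, −0.32, adjusted p = 1.18e-05), myofibril assembly (30 genes, −0.45, adjusted p = 6.21e-05), iron ion homeostasis (11 genes, −0.59, adjusted p = 0.000237) and carbon metabolism (98 genes, −0.27, adjusted p = 0.000795) in the second. With an estimated correlation 0 terms were called, with a smallest adjusted p = 0.996. Without mutant 1, mutant 2, sibling 1 or sibling 2 there were 45, 28, 9 and 243 called terms.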

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

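The setting of an adjusted p under 0.1, the other settings for annotation terms and the split by number were chosen after the data were seen. No gene was called by limma, and the count rose to 13 with a mean of at least 50, 8 after TMM scaling (1 higher, 7 lower), 16 with robust empirical Bayes and 7 at an adjusted p under 0.1, and stayed at 0 under the other settings without a block, every library left out included. The fold filter could only keep it at 0. The value of tie1 was −1.97 in each of the settings where it passed, which were a mean of at least 50, robust empirical Bayes and the replicate block. It stayed lower without each library, from −2.41 to −1.52, and its adjusted p over all settings ranged from 0.00138 to 0.902. Genes higher at an unadjusted p under 0.05 numbered 508 with no filter and 110 with a mean of at least 50, where more or fewer genes are tested, and genes lower 327 with that mean. Without each library in turn they numbered 185 to 352 higher and 154 to 394 lower, and in each such fit the lone library of a group is assumed to vary like the others. The cause of the other differences was not tested. The planned edgeR quasi-likelihood and DESeq2 tests were not run, since the rounded values do not give back reads. In simulated data with 2 libraries in each group 1.6% of genes changed 2-fold were called, and how much of this comes from depth and how much from the spread between pools was not tested.

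The 2 replicate numbers are shared by both groups, but nothing says that they pair the pools, and the deviations of equal numbers correlated at 0.20. With the replicate block, 95 genes were called, 19 higher and 76 lower, among them tie1 and myh7, each at an adjusted p of 0.00138, with 565 higher and 814 lower at an unadjusted p under 0.05. Calcium handling (adjusted p 0.016) and flow-responsive genes (0.045) were then called, BMP and TGF-beta genes turned direction at 0.86, and the block changed no other call of a list. Splitting the 4 libraries by number gave 0 called genes, 797 at an unadjusted p under 0.05 and 19 called lists, against 842 and 16 for the genotypes, and the remaining split gave 181 and 6. With 3 splits in all, no share of splits can be small. The split by number points to a structure of the libraries besides genotype. With number 2 subtracted from number 1 it moved the medians of the neural list by 0.80, sarcomere by 0.57, pan-endothelial by 0.52, erythrocytes by 0.04, basement membrane by −0.11, liver and yolk by −0.62 and skeletal muscle by −0.69, against 0.81, −0.56, −0.47, −1.26, −0.36, 1.0 and −1.17 for genotype. In the remaining split liver and yolk moved by −1.27, more in size than by genotype, and skeletal muscle by −0.62.

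With an estimated correlation 0 lists and 0 terms were called, and fry called 0 lists. With so few degrees of freedom, the estimated correlation left hardly any list or term able to pass. The lists that were called had, with an estimated correlation, adjusted p of 0.51 for erythrocytes and basement membrane, 0.67 for pharyngeal arch and 0.61 for the rest. With fry they had 0.19 for erythrocytes, 0.22 for basement membrane and for trabeculation, 0.31 for VEGF, 0.51 for skeletal muscle, 0.63 for Angiopoietin-Tie, matrix proteases, hypoxia and mitochondrially encoded genes, 0.65 for pan-endothelial, sarcomere, ribosomal proteins, leukocytes, liver and neural, and 0.84 for pharyngeal arch. BMP and TGF-beta turned direction with no filter (0.93), TMM (0.95) and fry (0.99), and Notch with quantile normalization (0.89) and fry (0.99). Matrix proteases lost their call with no filter (0.11), while calls were gained for calcium handling with no filter (0.025), flow-responsive genes with a pseudocount of 10 (0.048) and the cell cycle with quantile normalization (0.046). Quantile normalization also turned uncalled genes: myl7 0.01, myh6 0.25, nppa −0.11, cenpf 0.06, hsp90ab1 −0.02, gapdh 0.14, col2a1b 0.06 and krt4 0.09.

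Leaving out each library gave 8 to 20 called lists and 9 to 243 called terms, with 1 fewer library as the one difference. Adjusted p then ranged from 0.00036 to 0.12 for Angiopoietin-Tie, 2.2e-07 to 0.4 for pan-endothelial, 0.028 to 0.21 for VEGF, 0.011 to 0.46 for matrix proteases, 4e-08 to 0.079 for sarcomere, 0.038 to 0.12 for trabeculation, 1.8e-05 to 0.12 for hypoxia, 9.2e-18 to 0.56 for ribosomal proteins, 2.1e-07 to 0.071 for mitochondrially encoded genes, 6.2e-06 to 0.27 for neural, 0.0062 to 0.44 for leukocytes, 1.1e-17 to 0.85 for liver and yolk and 8.7e-05 to 0.55 for pharyngeal arch. For lists not called it ranged from 0.041 to 0.9 for endocardium, 0.005 to 0.93 for calcium handling, 0.12 to 0.46 for BMP and TGF-beta, 0.36 to 0.56 for Notch, 0.0036 to 0.98 for flow-responsive genes, 0.011 to 0.85 for oxidative phosphorylation, 0.018 to 0.91 for pigment cells, 0.37 to 0.85 for p53, 0.0029 to 0.98 for epidermis, 0.0028 to 0.89 for cardiac transcription factors and 5.3e-07 to 0.41 for the cell cycle. Erythrocytes, skeletal muscle and basement membrane were called in all 4. Among lists not called, endocardium, calcium handling, BMP and TGF-beta, Notch, p53, epidermis and pigment cells kept their direction in only 2 of these fits. Cardiac transcription factors, the cell cycle and oxidative phosphorylation kept theirs in 3.

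Named genes that were uncalled and changed sign without a library had these ranges of log2 fold change: bmp10 −0.34 to 0.56, nrg2a −0.25 to 0.24, nppa −0.5 to 0.6, adam10a −0.2 to 0.23, srgn −0.12 to 0.61, col2a1b −0.39 to 0.16, krt4 −0.33 to 0.17, has2 −1.16 to 0.26, nfatc1 −0.32 to 0.2, myl7 −0.6 to 0.37, myh6 −0.65 to 0.02, bmp4 −0.61 to 0.05, cenpf −0.38 to 0.16, hsp90ab1 −0.01 to 0.18, hspa5 −0.18 to 0.83, gapdh −0.4 to 0.28, sema3fb −0.41 to 0.01, apoc1 −0.37 to 1.55, apoa1b −0.04 to 1.39, col11a1a −0.13 to 0.3, fabp1b.1 −0.37 to 1.21, postnb −0.11 to 0.58, nrp1a −0.28 to 0.02, mki67 −0.18 to 0.54, rpl4 −0.03 to 0.47, tpm4a −0.42 to 0.19 and stat1a −0.23 to 0.33.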

Other observations

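All tests in this part were chosen after the results were seen. The genes nrg1, bmp10l and hey2, chosen after their values were seen, had both mutant values below both sibling values, as did 18.3% of all tested genes, against 16.7% by chance. The growth factor gene nrg1 had 9 and 7 against 25 and 27, bmp10l 8 and 23 against 65 and 31, and the transcription factor gene hey2 28 and 15 against 57 and 38. In the fixed trabeculation list, which holds nrg1 and bmp10l, 8 of 23 genes showed this and 1 the opposite, and in the Notch list, which holds hey2, 5 of 22 showed it and 5 the opposite, among them heyl, chosen in the same way, at 1.80 ± 0.59. The cytochrome P450 genes cyp1a and cyp1b1, also chosen after their values were seen and known as targets of the aryl hydrocarbon receptor, had 41 and 57 against 120 and 129, and 38 and 32 against 118 and 95. None of these 6 genes passed over all genes, with adjusted p in limma from 0.166 for cyp1b1 to 0.608 for hey2.

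Scaling of the libraries is argued against as the whole cause of the lower erythrocyte genes, since the median of the list stayed at or below −1.21 under TMM scaling and quantile normalization. A hypothesis is that the mutant pools held fewer erythrocytes. That would lower globin and other erythrocyte genes alike, and the 7 globin genes had a median of −1.24 and the other 15 a median of −1.40, with a permutation p across genes of 0.47 for the difference, which may also miss a small one. Of the 15, gata1a stood at −0.45 ± 0.35 and klf17 at 0.34 ± 0.30, with both mutant values of klf17 above both sibling values, which the hypothesis leaves unexplained. Lower levels of these genes in each erythrocyte would also move both sets alike, so this comparison cannot tell that from fewer cells. If such cells were fewer, whether fewer were in the heart or fewer stayed in it through the dissection was not tested.

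The low myh7 and myh7l values in the mutants were weighed against 3 technical explanations. A smaller share of heart muscle in the mutant pools would lower all heart muscle genes alike, but the log2 ratio of both to the geometric mean of the other 14 sarcomere list genes with a mean of at least 1000 was lower by −1.0 in the mutants, against a largest difference within a group of 0.24, with values from −1.27 against tpm4a to −0.51 against ttn.1 for single genes, of which 10 of 14 went beyond 2 times their own difference within a group. A loss of long transcripts would hit myh6 as well, and the log2 ratio of myh7 to myh6 differed by −1.12, against 0.21 within groups. That is a comparison with a single gene, and with an atrial one, while myh7 is ventricular. A smaller share of ventricle would lower this ratio too, so it cannot decide on transcript length. The titin genes were also lower relative to myl7. Their log2 ratios differed by −0.76 for ttn.1 and −0.43 for ttn.2, against 0.66 and 0.61 within groups, so some effect of transcript length stays open. Reads split between the neighbouring copies would leave their sum level, and the sum changed by −1.38. As both copies were lower on their own, the fall of the sum follows from the single values and is no separate test. The comparison with the other sarcomere genes covers heart muscle as a whole. The ratio of myh7 to myh6 was 0.883 and 0.761 in the mutants and 1.8 and 1.76 in the siblings. A smaller share of ventricle relative to atrium would lower it in this way, but was not tested apart from a change of myh7 itself. That share and the genotype stay open as explanations, and the genotype was not tested further.

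Thyroglobulin had the smallest p among the higher genes, although hearts do not make thyroid hormone and the thyroid lies near the outflow tract. Tissue carried along in 1 mutant pool alone is argued against, since without either mutant library the log2 fold change of tg stayed at 2.49 or above. As tg was named for a small p among genes whose groups do not overlap, this follows in part from the choice and is no separate test. A candidate explanation is thyroid tissue carried along in both mutant pools, but this cannot be told apart from other sources with these libraries. Of 7 other thyroid genes in the table, 2, nkx2.4b and pax8, were higher in both mutant libraries (one-sided exact binomial p = 0.33), nkx2.1 and nkx2.4a had values of 25 and 32 in mutant 1 and 0 in mutant 2, and foxe1, duox and slc26a4 were not higher in both. The gene pax2a, which is also used in the thyroid and was seen together with tg, had 45 and 32 against 7 and 6. The levels of most of these genes are near the floor, which keeps the question open. The neural list, like nkx2.1, nkx2.4a and nkx2.4b, was highest in mutant 1. Its medians were 1.56 in mutant 1, 0.52 in mutant 2, 0.44 in sibling 1 and −0.44 in sibling 2, and neural tissue as a source of these genes was not tested.

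As a mutant line is kept by selecting 1 allele, variants linked to tie1 could alter neighbouring genes. Within 10 Mb of tie1 on chromosome 6, 15 of 192 tested genes (7.8%) passed an unadjusted p under 0.05, against 6.9% of the rest, an odds ratio of 1.14 with a 95% interval from 0.62 to 1.94 (two-sided Fisher exact p = 0.57). An excess was not seen, but the interval allows one, so linkage cannot be told apart from none with this number of genes.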
